A study of Mus musculus with 2 samples.

How the data were processed

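RNA of the chromatin fraction of C57BL/6J bone marrow-derived macrophages was sequenced after ribosomal RNA depletion, in 2 libraries of 1 group, 0 minutes of lipid A at 100 ng/ml. Per the labels, fragments were 250 to 400 bases and the RNA input was 250 ng for replicate 1 and 500 ng for replicate 2. The labels call them biological replicates and give both the same donor entry, so it is not known whether they came from separate animals, and the spread between them may hold less than the variation between animals.

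The authors deposited a gene table and 2 transcript tables per library. Per the notes deposited with the files, the gene table and the first transcript table were made from an alignment to transcripts of GENCODE M21 on mm10, and the second transcript table from the reads and an index of the same transcripts. The column names have the layout of RSEM for the former and of kallisto for the latter, and the tools and their versions are not given in the sources used here. The deposited expected counts are estimated reads per gene or transcript, with reads that fit several places shared out, and are not whole numbers. The deposited TPM values divide expected counts by effective length and are scaled to a fixed sum per table. A posterior mean TPM is also in the deposited gene table, as is another value, the posterior SD of the count, which covers shared reads only and was not used in a result. Whether the library kit kept strand is not given in the sources used here, so a gene and an antisense or overlapping neighbour cannot be told apart.

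A phage control entry (phiX) held 0.338% and 0.27% of the gene table counts. It was left out of library sizes and tests, along with 96 spike-in entries and 26248 numbered entries. All 55536 genes of the annotation were found in the gene table by identifier, and 55450 in the second transcript table. Gene names, classes and coordinates were taken from that annotation. By counting error alone a count of 0 allows up to 3 counts, or 0.274 and 0.212 RPM in replicates 1 and 2, which does not bound reads that the tables assign to another gene. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

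Before the data were examined, gene lists for 17 programs and 11 other cell types, the tests, the alternatives and the rule for naming genes were fixed. The rule named the 15 most abundant nuclear protein-coding and 10 most abundant long non-coding genes, the 4 highest and 2 lowest members of each program list, the 2 highest members of each list of another cell type, the 5 largest and 5 smallest log2 ratios between replicates among genes with a mean of at least 50 counts, and the 5 highest retained-intron shares among genes with at least 500 counts in each replicate. Some genes that the rule takes are not named in the text. Where several members of a list had no read, the choice among them was arbitrary. Cdh5, CT010467.1, Scarna2, mt-Co2, Gm28437 and the members of the lists of cholesterol synthesis, LXR target, SR protein and CLK, and Y-linked genes were named outside the rule, after values were seen.

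A gene was called detected at 1 TPM or more in both replicates. The level of a list was the median over members of the mean TPM, with the SD of the 2 replicates' medians. Its percentile is that of the median log2(TPM + 1) among 10000 random lists of the same size from protein-coding genes, or from all genes for the 3 lists of non-coding genes. Expected counts were rounded to whole numbers for edgeR 4.0.16 and DESeq2 1.42.0 in R 4.3.3. Common dispersion was estimated with an intercept only, TMM scaling and edgeR's filter on low counts. Log2 ratios are of replicate 2 over replicate 1, on TMM-scaled expected counts plus 0.5. The median log2 ratio of a list, over members with a mean of at least 10 counts, was set against 10000 random lists of the same size matched on mean counts in 20 bins. These percentiles describe the 2 libraries and are no test of a condition. With 17 lists, chance alone would put some outside the central 95%. The retained-intron share was taken from the first transcript table. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for all else.

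The steps were tested on simulated data at the real means and library sizes. A simulated coefficient of variation of 0.1 came back as 0.0994 with no changed genes, and as 0.137 with 200 genes changed by 2-fold or 4-fold. Of the 4-fold changes that kept a mean of 50 counts, 100% passed the 2-fold rule, and of the true 2-fold changes 44.8%. Over 1000 simulated lists of 20 members, 4.7% of unchanged lists lay outside the central 95% and 100% of lists shifted by 0.5 on the log2 scale did. For list levels, 5.8% of unchanged lists lay outside it and 60.6% of lists raised by 3 on the log2 scale lay above it. For list differences the simulation covered only lists of 20 members, from genes with a mean of at least 50 counts. Shorter lists and members below that mean were not tested in this way. The late endotoxin-inducible list, with 7 members and too few at a mean of 50 counts, is such a case. Smaller runs of 50 and 200 lists had come first and put more unchanged lists outside the range for list differences, so their number was raised after that was seen.

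Alternatives covered the TPM threshold (0.1 and 5), a minimum of 10 counts, a pseudocount of 0.1, a TPM filter of 10 or none, DESeq2 size factors, library totals, a mean of 10 or 500 counts, TPM rescaled over nuclear protein-coding genes, posterior mean TPM, random lists of detected genes only, shares of counts, a minimum of 1000 counts for retained introns, the second transcript table, and each replicate alone. A value without a test was called moved when it changed by more than 1 SD of the replicates. Where the value is the mean of the 2 replicates, each replicate alone always lies within 1 SD, so it could not move. For list percentiles a change of 1 point, the sampling error of the random lists, was also allowed, and for the coefficient of variation, which has no replicate SD, a change of 10%. For Pearson's r the SD came from resampling genes. These tolerances were not part of the plan, and changes of side of the central 95% were given for list differences after a first look at the output.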

Results

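Chromatin-associated RNA was measured in mouse bone marrow-derived macrophages, cells grown from the marrow of C57BL/6J mice, at the 0-minute point of a stimulation with lipid A (100 ng/ml), the part of bacterial endotoxin that activates Toll-like receptor 4. The chromatin fraction holds RNA still attached to its template, much of it not yet spliced. Ribosomal RNA was depleted and total RNA was sequenced in 2 biological replicates, prepared from 250 ng (replicate 1) and 500 ng (replicate 2) of RNA. Both belong to 1 group, so no treated group was compared with an untreated one and no p-value is given for a condition. The gene tables summed to 10970767 expected counts in replicate 1 and 14207280 in replicate 2. Unless stated otherwise, values are length-normalised transcript abundances (TPM) as the mean ± SD of the 2 replicates (n = 2), and coordinates are on mm10.

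The 15 most abundant nuclear protein-coding genes were of several kinds. Gpnmb, a lysosome-associated glycoprotein gene (ENSMUSG00000029816.10, chromosome 6, 49036546 to 49070929), ranked first at 1418 ± 145 TPM. Among the 15 highest were the lysosomal genes Tcirg1, a proton pump subunit (chromosome 19, 3896050 to 3907133, 887 ± 136 TPM), Psap, the saposin precursor (chromosome 10, 60277627 to 60302597, 835 ± 136 TPM), and Ctsb, cathepsin B (chromosome 14, 63122462 to 63145923, 572 ± 89.4 TPM). RNA-binding and splicing genes in the same set were Hnrnpa2b1 (818 ± 5.54 TPM), Ddx5 (757 ± 81.5 TPM), Rbm39 (631 ± 41.2 TPM), Srsf5 (559.8 ± 61.9 TPM) and Rsrp1 (875 ± 62.8 TPM). Stab1, a scavenger receptor gene, stood at 757 ± 171 TPM, the transcriptional repressor gene Zeb2 at 753 ± 108 TPM, Sat1 at 743 ± 53.8 TPM and Xdh at 625 ± 98.1 TPM. The neighbouring paralogs Lilrb4a (1031 ± 75.6 TPM) and Lilr4b (684 ± 4.99 TPM) share sequence, so the split between them is uncertain. In all, 10292 of 22028 annotated protein-coding genes reached 1 TPM in both replicates, as did 1496 of 10155 long non-coding genes and 14018 of 55536 annotated genes.

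**Figure D1:**
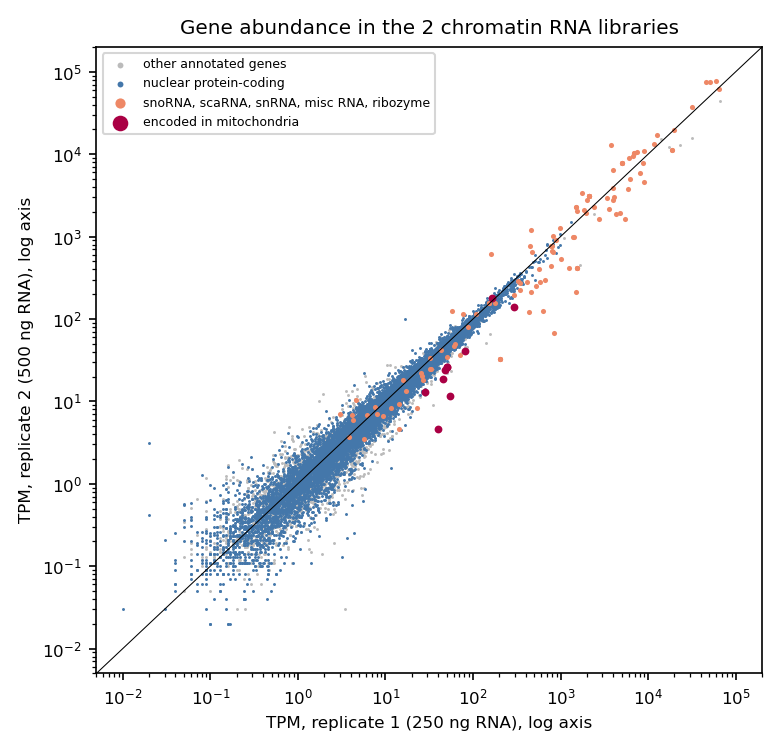
Each point is a gene with at least 10 expected counts over both replicates and a TPM above 0 in each, placed by its TPM in replicate 1 and in replicate 2 on log axes, and the line marks equal values. The mitochondrial genes mt-Rnr1, mt-Rnr2 and mt-Co1 (293 and 140 TPM) lie below the line.

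Macrophage identity genes were abundant, and markers of other cell types were mostly near 0 in the gene table. Of 25 macrophage identity genes, 24 reached 1 TPM in both replicates, with a list median of 40.6 ± 5.62 TPM. The highest were Lgals3 (galectin-3, 224 ± 3.79 TPM in the gene table, at least 2-fold higher in the second transcript table and so uncertain), Lyz2 (lysozyme, 176 ± 20.6 TPM), Csf1r (the receptor of the growth factor CSF1, chromosome 18, 61100598 to 61132149, 173 ± 16.9 TPM) and the transcription factor gene Irf8 (127 ± 22.5 TPM). Cebpb was lower at 5.14 ± 1.56 TPM. The fractalkine receptor gene Cx3cr1 held 1 expected count in each replicate and was the member that was not detected, although the second transcript table gave it more. All 22 lysosome and lipid handling genes were detected, with a median of 80.4 ± 11.4 TPM. After Psap and Ctsb came Ctsd (354 ± 46.1 TPM) and Grn (281 ± 29.8 TPM), and Scarb1 (28.1 ± 3.30 TPM) was among the lowest. Both list medians exceeded those of all 10000 random lists of protein-coding genes.

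Across the 11 lists of other cell types, 11 of 86 markers reached 1 TPM in both replicates, and 39 had no read in either. The list medians ran from 0 TPM for natural killer cell, erythroid, mast cell and basophil, and epithelial markers to 0.203 ± 0.0247 TPM for dendritic cell markers. Between them lay T cell (0.0175 ± 0.0247 TPM), neutrophil (0.0275 ± 0.0177 TPM), endothelial (0.0475 ± 0.0389 TPM), B cell (0.0500 ± 0.0354 TPM), stromal (0.0525 ± 0.0247 TPM) and megakaryocyte (0.170 ± 0.226 TPM) markers, and with such spreads their order is not resolved. Megakaryocyte markers had 0.340 TPM in replicate 1 and 0.0200 in replicate 2. In the second transcript table the medians were higher for most of these lists, with 1.17 TPM for dendritic cell, 1.10 for T cell, 0.844 for megakaryocyte, 0.670 for endothelial, 0.549 for B cell, 0.361 for stromal and 0.269 for neutrophil markers. Vwf, which encodes von Willebrand factor and stood in the endothelial list, was the exception at 50.7 ± 0.983 TPM (chromosome 6, 125546774 to 125686679), with 2057 and 3055 expected counts. Kdr, in the same list, was at 2.54 ± 0.87 TPM, and Cdh5, the endothelial cadherin gene, had no read. Other markers above the threshold were Alas2 (8.4 ± 3.79 TPM) and Epor (2.49 ± 0.255 TPM) of the erythroid list, Pf4 (7.74 ± 6 TPM) and Itga2b (1.82 ± 1.15 TPM) of the megakaryocyte list, Cd4 (7.43 ± 0.771 TPM) and Cd5 (2.27 ± 0.12 TPM) of the T cell list, Batf3 (5.33 ± 1.82 TPM) and Zbtb46 (1.57 ± 0.141 TPM) of the dendritic cell list, and Cr2 (1.22 ± 0.219 TPM, at least 2-fold higher in the second transcript table) of the B cell list, in which Fcrla was next (0.280 ± 0.212 TPM). Neutrophil markers were led by Mmp8 (0.555 ± 0.0919 TPM) and S100a9 (0.355 ± 0.502 TPM), stromal markers by Acta2 (0.47 ± 0.099 TPM) and Col1a2 (0.435 ± 0.00707 TPM), and mast cell markers by Cpa3 (0.065 ± 0.0212 TPM) and Ms4a2 (0.015 ± 0.0212 TPM). Fcrla, Cpa3 and Ms4a2 were at least 2-fold higher in the second transcript table, which gave Cpa3 1.24 and 1.29 TPM. Eomes and Gzma of the natural killer list and Cdh1, Epcam, Krt8 and Krt18 of the epithelial list had no read. Here and below, no read refers to the gene table, and the second transcript table gave reads to some of these genes, Eomes and Epcam among them. By counting error alone a count of 0 allows 0.274 RPM (reads per library size, scaled to the same sum as TPM but not divided by length) in replicate 1 and 0.212 in replicate 2 (3 counts of the total). RPM is not on the TPM scale: 3 counts of the small RNA host gene Epb41l4aos were 1.49 TPM in replicate 1. This floor is also no limit on reads assigned to another gene: Eomes, at 0 in the gene table, had 40.3 and 57.3 counts in the second transcript table.

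The components of endotoxin sensing were present, whereas most genes that endotoxin switches on late were at or near 0 in the gene table. Of 24 genes of the Toll-like receptor 4 (TLR4) pathway, 23 were detected, with a list median of 20.2 ± 0.824 TPM. The highest were the kinase genes Ikbke (chromosome 1, 131254343 to 131279606, 306 ± 44.4 TPM), Tbk1 (99.2 ± 16.7 TPM) and Chuk (88.5 ± 2.55 TPM) and the transcription factor gene Irf3 (83.0 ± 4.54 TPM). Tab3 was at 4.01 ± 0.269 TPM and Lbp at 0.485 ± 0.233 TPM. Both were at least 2-fold higher in the second transcript table. All 12 NF-kB subunit and inhibitor genes were detected (median 11.2 ± 0.265 TPM), from Nfkb1 (52.9 ± 3.49 TPM), Nfkb2 (16.7 ± 1.36 TPM), Rela (15.4 ± 2.45 TPM) and Bcl3 (13.1 ± 3.25 TPM) down to Nfkbib (3.27 ± 0.269 TPM) and Nfkbie (2.53 ± 0.205 TPM).

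Early endotoxin-inducible genes had a median of 3.69 ± 0.481 TPM, and 15 of 20 were detected. Plk2 (65.7 ± 4.82 TPM), Zfp36 (22.6 ± 1.23 TPM), an mRNA decay factor gene, and the chemokine genes Ccl4 (19.3 ± 2.55 TPM) and Ccl3 (16.9 ± 3.46 TPM) were the highest. Ptgs2, which encodes cyclooxygenase-2, was at 0.115 ± 0.00707 TPM, and Cxcl3 had no read. Late endotoxin-inducible genes had a median of 0.107 ± 0.046 TPM, and of 0.880 TPM in the second transcript table. Of these 20 genes, 5 were detected and 7 had no read in either replicate, Lcn2 and Lif among them. The highest were Ccl5 (2.63 ± 0.658 TPM), Acod1 (2.44 ± 0.46 TPM), Ebi3 (2.13 ± 1.08 TPM) and Il1rn (1.69 ± 0.544 TPM), each resting on 9 to 102 expected counts per replicate. Of 16 immediate early genes 13 were detected (median 3.61 ± 0.357 TPM), led by Klf6 (47.7 ± 3.73 TPM), Atf3 (35.2 ± 1.62 TPM), Jun (18.4 ± 1.65 TPM) and Junb (13.7 ± 0.728 TPM), while Fosb (0.72 ± 0.0283 TPM) and Klf4 (0.28 ± 0.0283 TPM) were the lowest.

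Interferon response genes were higher than either inducible list, with 20 of 22 detected and a median of 21.7 ± 0.559 TPM. Stat2, which encodes a transcription factor of interferon signalling (174 ± 30.8 TPM), Mx1 (75.0 ± 20.0 TPM) and Ddx58, the RIG-I sensor gene (59.3 ± 4.77 TPM), were among the highest. Isg15 was at 2.26 ± 0.0141 TPM, and the interferon beta gene Ifnb1 had no read in either replicate. Alternative activation genes were split: Il4ra (41.7 ± 3.85 TPM), Clec7a (39.8 ± 6.1 TPM), Pparg (22.5 ± 0.488 TPM, at least 2-fold higher in the second transcript table) and Clec10a (13.2 ± 1.04 TPM) were the highest of 6 detected genes, and the other 6 were not detected, with no read for Retnla or Ccl17. Their median was 1.16 ± 0.272 TPM, and 3.98 TPM in the second transcript table. As percentiles of the random lists of protein-coding genes, the medians lay at 100.0 for the TLR4 pathway, 98.6 for NF-kB genes, 99.99 for interferon response, 87.3 for early and 18.9 for late inducible genes, 84.8 for immediate early genes and 56.02 for alternative activation. Among random lists of detected genes only, the TLR4 pathway lay at 97.4, interferon response at 98.4 and NF-kB genes at 51.7. Immediate early genes lay at 0.14 there, early inducible genes at 0.02, and late inducible and alternative activation genes at 0. The lists kept their undetected members, so a low place there was in part set by construction. For late inducible genes, with a median below 1 TPM, it was wholly so.

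Ribosomal protein genes had a median of 25.7 ± 3.32 TPM, with all 25 detected. They ran from Rpl10 (114 ± 7.33 TPM), Rpl3 (103 ± 1.85 TPM), Rps9 (73.6 ± 17.6 TPM) and Rpl5 (47.3 ± 2.41 TPM) down to Rplp0 (10.04 ± 1.66 TPM) and Rpl32 (6.47 ± 0.983 TPM). Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. The 14 housekeeping genes were all detected (median 29.8 ± 0.0601 TPM), among them Actb (167 ± 34 TPM), Eef1a1 (162 ± 18.3 TPM) and Sdha (60.8 ± 2.01 TPM), with Pgk1 (5.78 ± 0.226 TPM) lowest. Cell cycle genes had a median of 2.71 ± 0.233 TPM with 17 of 20 detected, led by Pcna (21.4 ± 0.163 TPM), Top2a (7.84 ± 0.0212 TPM), Mcm6 (6.74 ± 1.77 TPM) and Mki67 (6.37 ± 0.827 TPM), with Plk1 (0.825 ± 0.0919 TPM) and Ccnb2 (0.275 ± 0.0354 TPM) lowest. In the second transcript table the cell cycle median was 4.78 TPM. Replication-dependent histone genes had a median of 2.77 ± 0.212 TPM with 15 of 17 detected. Hist2h2ac (17.6 ± 1.82 TPM), Hist3h2a (12.7 ± 1.04 TPM), Hist1h1c (7.48 ± 0.686 TPM) and Hist1h2bg (7.27 ± 0.191 TPM) were the highest, and Hist1h3c (0.640 ± 0.905 TPM) and Hist1h1d (0.595 ± 0.00707 TPM) the lowest. Their near-identical copies make single values uncertain. The percentiles were 100.0 for ribosomal protein and housekeeping genes, 81.3 for cell cycle genes and 79.9 for histone genes. Among random lists of detected genes only, the cell cycle median lay at 0 and the histone median at 0.03. Both lists kept their undetected members, which lowers their place there.

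Reads and TPM gave different pictures of the RNA classes. Nuclear protein-coding genes took 61.4 ± 3.36% of expected counts and long non-coding genes 33.5 ± 2.98%. In TPM, which divides by effective length, snoRNA and scaRNA genes (guide RNAs for RNA modification) took 37.5 ± 2.98% from 0.427 ± 0.0168% of the counts in the first transcript table and 6.27% of TPM in the second, and nuclear protein-coding genes took 25.4 ± 1.14%. Long non-coding genes took 11.9 ± 2.82% of TPM, snRNA genes 9.33 ± 1.99%, ribozyme genes 7.01 ± 1.20%, misc_RNA genes 4.59 ± 0.846%, rRNA genes 2.38 ± 1.11%, pseudogenes 0.939 ± 0.124% and genes annotated as TEC, to be experimentally tested, 0.896 ± 0.0928%. In the second transcript table miRNA genes took 41.3% and 16.8% of TPM in replicates 1 and 2, against 0.041 ± 0.00871% in the first, and pseudogenes 7.69%. Both tables came from the same libraries, and snoRNA and scaRNA genes held 0.339% of the counts in the second. For this reason a TPM here depends on how each table treats short RNAs. These TPM shares do not measure how much short RNA the libraries held. The long non-coding gene Gm26917 (chromosome 17, 39843013 to 39846341) alone held 19.3% of counts in replicate 1 and 14.8% in replicate 2. It lies beside Gm42418 and CT010467.1, annotated as rRNA, at a copy of ribosomal DNA, and these 3 genes together held 23.4% and 17.7% of counts. Left out of the total, an alternative chosen after the data were seen, they leave long non-coding genes at 17.8% and 17.6% of counts.

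**Figure D2:**
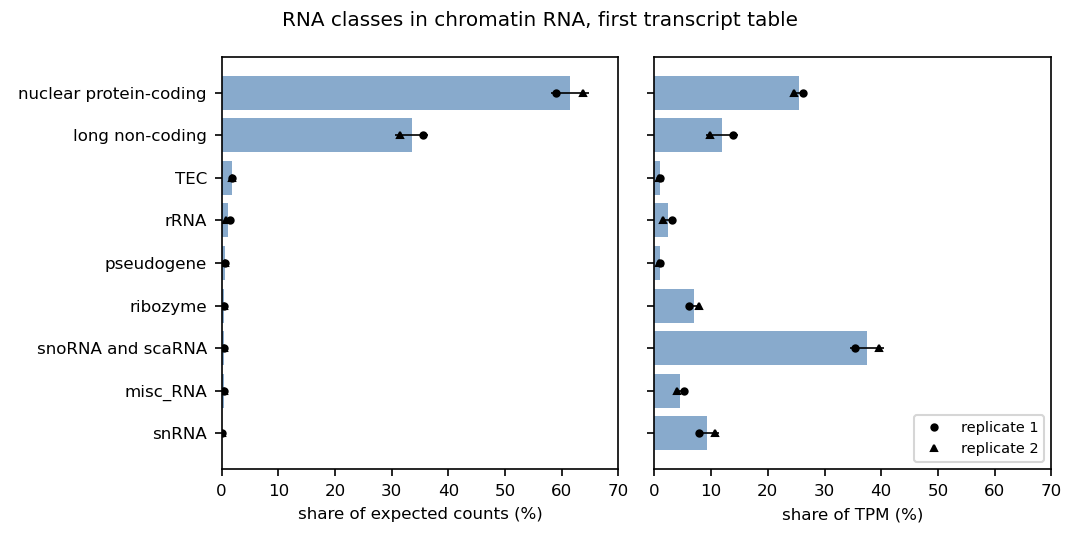
Bars give the mean share (%) of expected counts (left) and of TPM (right) by annotated RNA class, from the first transcript table, with the SD over the 2 replicates as error bars and each replicate as a point. Nuclear protein-coding genes fall from 61.4% of counts to 25.4% of TPM, and snoRNA and scaRNA genes rise from 0.427% to 37.5% (6.27% of TPM in the second transcript table).

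Nuclear long non-coding RNAs known to stay at chromatin or in nuclear bodies were among the most abundant single genes. Malat1 (chromosome 19, 5795690 to 5802672) held 960841 and 1334550 expected counts, Neat1, the scaffold of paraspeckles (chromosome 19, 5824708 to 5845478), held 149549 and 205331 and stood at 2122 ± 374 TPM, and Xist, the RNA that coats the inactive X chromosome (chromosome X, 103460366 to 103483254), held 161052 and 214110 and stood at 1029 ± 85.7 TPM. Lncpint (218 ± 15.2 TPM) and Firre (166 ± 22 TPM) followed. Of 16 nuclear long non-coding RNAs on the list 11 were detected (median 16.5 ± 0.969 TPM), and Miat and Rmst had no read. All 11 hosts of small RNAs were detected (median 15.9 ± 2.14 TPM), led by Gas5 (143 ± 4.91 TPM), Snhg1 (29.0 ± 4.79 TPM), Zfas1 (25.5 ± 0.686 TPM) and Snhg15 (20.7 ± 1.31 TPM), with Snhg3 (3.10 ± 2.5 TPM) and Epb41l4aos (1.42 ± 0.099 TPM) lowest. Epb41l4aos rested on 3 and 4 counts and was at least 2-fold higher in the second transcript table, so its level is uncertain. Gm23925 and Gm12238 ranked among the 10 most abundant long non-coding genes by TPM on 35 and 12 counts and on 4 and 2 counts, so their TPM values are not given. Of 16 small structural RNAs 9 were detected (median 20.1 ± 11.6 TPM, and 5.28 TPM in the second transcript table). Another 6, among them the RNase P RNA copies Rprl2 and Rprl3, had no read. The highest were Rmrp, the RNA of RNase MRP (38486 and 69233 counts), Rn7sk, the 7SK RNA (13858 and 27153), and Rn7s1 and Rn7s2, copies of the 7SL RNA of the signal recognition particle (16286 and 13580 for each copy). Rmrp is annotated under 2 overlapping gene entries, and the other one, a long non-coding entry, held 16638 and 12996 counts. That overlap and the even split of 7SL counts over identical copies make these values uncertain, and all 4 had an at least 2-fold lower TPM, though not lower counts by that much, in the second transcript table.

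A large part of the signal of protein-coding genes was assigned to transcripts annotated as retained intron. Of all expected counts on nuclear protein-coding genes, 25.1 ± 0.0954% went to such transcripts and 67.8 ± 0.0584% to protein-coding transcripts. Over 5042 genes with at least 100 counts in each replicate and an annotated retained-intron transcript, the median share of a gene's TPM on these transcripts was 49.3% in replicate 1 and 48.5% in replicate 2 (48.9 ± 0.566%). The share was 50% or more in 2426 genes. The gene shares had a Spearman's rho of 0.942 between the replicates, across genes, which are not independent replicates. The highest shares among genes with at least 500 counts were those of Bbs10 (100.0%, chromosome 10, 111298679 to 111301727), Lilrb4a (99.9 ± 0.056%), Ccdc59 (98.7 ± 0.23%), Rbm4b (98.6 ± 0.16%) and Slc27a1 (98.4 ± 1.1%). By list, the median share was 71.9% for 16 ribosomal protein genes (70.7% and 72.3% in replicates 1 and 2), 55.1% for 9 housekeeping genes (55.0% and 56.1%) and 32.0% for 8 NF-kB genes (35.5% and 31.0%). Between these lay TLR4 pathway (15 genes, 54.7% and 49.0%), interferon response (10 genes, 45.8% and 49.3%), lysosome (15 genes, 46.9% and 51.0%) and macrophage genes (8 genes, 42.6% and 38.2%), and the order of TLR4, interferon and lysosome genes differed between replicates. Measured in counts instead of TPM the median share was 31.1 ± 0.723%, and reads from introns with no annotated transcript were not counted. Reads of RNA not yet spliced can also be assigned to such transcripts, so the share does not tell retained introns from unfinished splicing.

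The replicates were compared gene by gene to see how far 2 preparations of the same kind differ. Pearson's r of log2(TPM + 1) was 0.94 and Spearman's rho 0.939 across the 15556 genes with at least 1 TPM in either replicate, and r was 0.981 over the 10844 nuclear protein-coding genes among them, a subset chosen after the data were seen. The biological coefficient of variation, from edgeR's common dispersion over 14576 genes, was 0.0977. The median chi-square of the scaled counts was 1.22 per gene (0.455 under counting noise alone). Of 10984 genes with a mean of at least 50 counts, 41 differed by 2-fold or more, 18 higher in replicate 2 and 23 higher in replicate 1. With library totals in place of TMM scaling, which moves all log2 ratios up by 0.13, 37 were higher in replicate 2 and 18 in replicate 1. With TMM scaling, 14 nuclear protein-coding genes were higher in replicate 2 and 6 in replicate 1. In simulated replicates with a coefficient of variation of 0.1, 0.0835% of unchanged genes passed this rule, against 0.373% observed. The simulation gave every gene the same coefficient of variation, so the excess does not show that single genes truly differ. Observed genes with a mean of 50 to 100 counts passed in 1.08% of cases, and those with 500 to 2000 counts in 0.108%.

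The mitochondrial ribosomal RNAs had large differences in both the gene table and the second transcript table. mt-Rnr2 had 559 and 96 counts, a log2 ratio of replicate 2 over replicate 1 of -3.04 (95% exact binomial interval -3.37 to -2.73, counting error only), and mt-Rnr1 408 and 128 counts, a log2 ratio of -2.17 (-2.47 to -1.88). In the second transcript table the ratios were -2.63 and -2.16. Both libraries had been depleted of ribosomal RNA, and whether the depletion differed between them was not tested. The genes at the ribosomal DNA copy were also lower in replicate 2, with Gm26917 at -0.52, CT010467.1 at -0.95 and Gm42418 at -0.44. Several other genes at the extremes share or overlap sequence with another gene. Rnu3a, a U3 snoRNA gene, had 270 counts in replicate 1 and 0 in replicate 2 of the gene table but 1383 and 698 in the second transcript table (log2 ratio -1.47), and Rnu3b1 467 and 169 (log2 ratio -1.97, and 0.58 in the second transcript table). Gm26992, which overlaps Xist, had 131 and 0 counts, and 691 and 103 in the second transcript table (log2 ratio -3.22). The readthrough gene Gm20388 had 1 and 178, with a log2 ratio of 6.52 (4.48 to 12.3) in the gene table and -0.56 in the second transcript table. Gm25776 (log2 ratio 1.60), Gm12183 (1.53), Chtf8 (1.41) and Tpgs2 (1.31) were the next highest in replicate 2. Chtf8 was at 0.59 and Tpgs2 at 0.07 in the second transcript table, neither of them 2-fold. The levels of all 4 genes differed at least 2-fold between the tables.

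Of 17 program lists, 4 had a median log2 ratio between replicates outside the central 95% of 10000 random lists matched on mean counts. Mitochondrially encoded protein genes were lower in replicate 2 (median -0.94 over 8 members, 7 of them lower, lower than every random list). mt-Co1 had 3960 and 2831 counts (log2 ratio -0.99), mt-Nd6 a ratio of -0.95 and mt-Nd1 of -0.90. mt-Atp8, on 41 and 59 counts, had a ratio of 0.02. Another 5 members, mt-Nd3 and mt-Nd4l among them, were not detected in the gene table. Small structural RNAs were also lower (median -0.64 over 8 members, and -0.24 with members at a mean of 50 counts or more). Of the 5 lower members, 2 are the identical copies of 7SL at -0.76, which hold the same counts. Among the 3 higher were 7SK at 0.47 and Rmrp at 0.34, but the overlapping Rmrp entry had -0.86, so the direction for Rmrp depends on how reads were split. This list lay at the 20.9 percentile in the second transcript table, inside the range. Lysosome and lipid handling genes had a median of -0.18, with 16 of 22 members lower in replicate 2 (Psap at -0.26, Ctsb at -0.17), below all random lists. In the second transcript table they were at -0.11, still below the central 95%. Late endotoxin-inducible genes had a median of 0.46 over 7 members, 4 higher and 3 lower, at the 98.0 percentile, and lay at the 72.4 percentile in the second transcript table. With library totals these 4 medians were -0.81, -0.51, -0.05 and 0.59. The other 13 lists lay inside the range, but in the second transcript table early inducible (percentile 99.99), interferon response (99.64) and housekeeping genes (99.84) lay above it. Their medians were 0.12 for early inducible, 0.11 for housekeeping, 0.10 for histone, 0.08 for TLR4 pathway and for interferon response, 0.05 for small RNA host, 0.01 for immediate early and 0.00 for cell cycle genes. On the other side of 0 were NF-kB (-0.01), long non-coding (-0.02), ribosomal protein (-0.06), alternative activation (-0.08) and macrophage identity genes (-0.08), and all 5 turned positive with library totals. Replicate and RNA input amount cannot be told apart here.

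**Figure D3:**
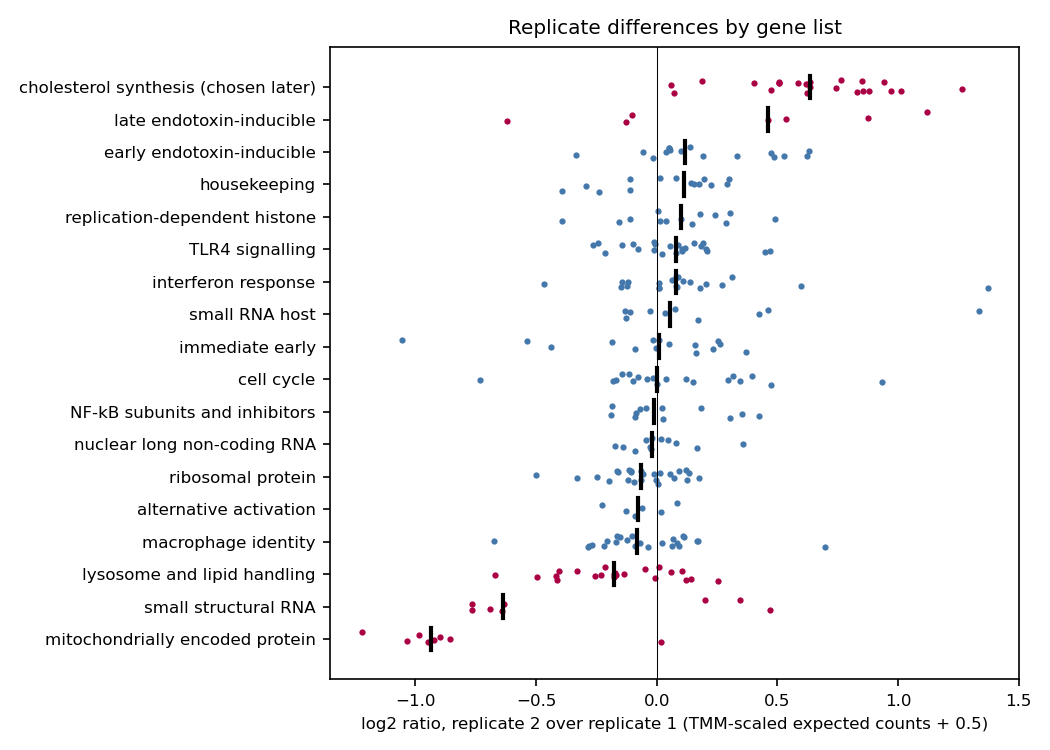
Points are list members with a mean of at least 10 expected counts, placed by their log2 ratio of replicate 2 over replicate 1, with black bars for list medians and red for the 4 lists outside the central 95% of matched random lists and the cholesterol synthesis list chosen after the data were seen. Mitochondrially encoded protein genes have a median of -0.94 and cholesterol synthesis genes of 0.63.

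The gene table and the second transcript table give each gene a value made in different ways. Spearman's rho between the gene table and the second transcript table summed per gene was 0.578 in replicate 1 and 0.612 in replicate 2, over genes with at least 1 TPM in either table. Over the 10292 protein-coding genes detected in the gene table, a set that differs in both class and filter, it was 0.926 in each replicate. The second table held 1.75 and 1.74 times as many counts. Of 23751 genes, 8976 differed by 2-fold or more in both replicates, 8737 of them higher in the second table. Among the detected protein-coding genes 732 did so.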

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

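Entries of the gene table outside the annotated genes held reads above the 3 counts that a count of 0 allows. There was no control sample to compare with. The phage control entry (phiX, a control genome often added to sequencing runs) held 37048 counts in replicate 1 and 38381 in replicate 2. A block of 26248 numbered entries, whose content the files do not state, held 11 and 13 counts. The 96 spike-in entries held 0 in each.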

How the results depend on the processing

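No paired analysis was possible because there is only 1 group. The alternatives without the ribosomal DNA copy and with nuclear protein-coding genes alone were chosen only after the result was seen. The count of detected protein-coding genes stayed within 1.5 times under each alternative run, from 7239 at 5 TPM to 12449 at 0.1 TPM, and the coefficient of variation ran from 0.0942 to 0.102. The count of long non-coding genes changed by more than 1.5 times, up at 0.1 TPM and in the second transcript table and down at 5 TPM. That of all annotated genes did so at 5 TPM, downward. Pearson's r was 0.874 with a pseudocount of 0.1, 0.874 with a filter of 10 TPM, 0.966 with no filter and 0.959 in the second transcript table. The count of genes differing 2-fold was 41 with DESeq2 size factors, 55 with library totals and 60 in the second transcript table, against 441 at a mean of 10 counts, 3 at a mean of 500 counts and 20 among nuclear protein-coding genes.

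List percentiles among random lists of detected genes only, a higher pool by construction, were 0 for late endotoxin-inducible, alternative activation, cell cycle, neutrophil, T cell, B cell, NK cell, dendritic cell, erythroid, megakaryocyte, mast cell and basophil, fibroblast and stroma, endothelium and epithelium. Undetected members were kept in the lists, so a list with a median below 1 TPM could only lie at 0. The percentiles were 97.4 for TLR4 signalling, 51.7 for NF-kB subunits and inhibitors, 0.02 for early endotoxin-inducible, 0.14 for immediate early, 98.4 for interferon response, 95.2 for nuclear long non-coding RNA, 90.2 for small RNA host, 82.9 for small structural RNA, 98.9 for mitochondrially encoded protein and 0.03 for replication-dependent histone. In the second transcript table they were 69.98 for early endotoxin-inducible, 61.3 for immediate early, 70.7 for alternative activation, 49.05 for replication-dependent histone, 30.4 for T cell, 7.51 for NK cell, 31.3 for dendritic cell, 1.76 for mast cell and basophil, 11.5 for fibroblast and stroma and 9.11 for epithelium. With posterior mean TPM, which is above 0 for genes without reads, they were 82.05 for early endotoxin-inducible, 80.9 for immediate early, 70.2 for replication-dependent histone, 27.4 for T cell, 43.9 for B cell, 6.49 for NK cell, 18.3 for dendritic cell, 27.2 for erythroid, 19.9 for megakaryocyte, 7.79 for mast cell and basophil, 35.7 for fibroblast and stroma, 23.1 for endothelium and 2.43 for epithelium. From each replicate alone they were 17.7 to 21.7 for late endotoxin-inducible, 82.7 to 85.6 for immediate early, 79.9 to 81.3 for replication-dependent histone, 5.27 to 15.1 for neutrophil, 10.04 to 25.3 for B cell, 11.4 to 12.04 for NK cell, 5.71 to 6.21 for erythroid, 11 to 11.6 for mast cell and basophil, 18.1 to 22.4 for fibroblast and stroma, 17.96 to 22.3 for endothelium and 6.91 to 7.28 for epithelium. The other lists stayed within 1 SD of the replicates or 1 point, which for T cell (5.37 to 16.5) and megakaryocyte (24.4 to 42.1) is a wide range. That SD comes from the same replicates, so staying within it is no sign of stability. With rescaled TPM all 28 percentiles stayed within the tolerance. That was close to fixed by construction, since rescaling multiplies all genes of a library by the same factor.

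Median log2 ratios of lists in the second transcript table were -0.0225 for macrophage identity, -0.11 for lysosome and lipid handling, 0.10 for NF-kB subunits and inhibitors, 0.25 for early endotoxin-inducible, 0.0344 for late endotoxin-inducible, 0.13 for interferon response, -0.0536 for small structural RNA and 0.17 for housekeeping. By these, late endotoxin-inducible and small structural RNA came inside the central 95%, and early endotoxin-inducible, interferon response and housekeeping came outside it, at percentiles 99.99, 99.64 and 99.84. At a mean of 50 counts small structural RNA was at -0.24, and the late endotoxin-inducible list had too few members for a value.

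Shares by class as percent of counts were 1.9 for TEC, 33.5 for long non-coding, 0.408 for misc_RNA, 61.4 for nuclear protein-coding, 1.12 for rRNA, 0.44 for ribozyme, 0.124 for snRNA and 0.427 for snoRNA and scaRNA. As TPM in the second transcript table they were 1.64 for TEC, 1.97 for misc_RNA, 31.2 for nuclear protein-coding, 4.49 for rRNA, 2.32 for ribozyme, 3.39 for snRNA and 6.27 for snoRNA and scaRNA. Among classes below 1% in the first table, miRNA rose to 29.0 and pseudogene to 7.69 there. Without the ribosomal DNA copy TPM shares were 0.99 for TEC, 5.41 for long non-coding, 28.1 for nuclear protein-coding, 0.0144 for rRNA and 41.3 for snoRNA and scaRNA. The median retained-intron share was 31.1% in counts, 46.2% at 1000 counts and 46.1% in the second transcript table. Spearman's rho between the tables was 0.454 at 10 TPM. Of the levels of 159 named genes, 112 (70 higher, 42 lower) changed by more than 1 SD in the second transcript table, 70 (40 higher, 30 lower) with posterior mean TPM and 141 (141 higher, 0 lower) with rescaled TPM. Rescaling raises every value above 0, so the rise with rescaled TPM was fixed by construction. The cause of the other shifts was not tested beyond the constructions named. The ratios of genes with few counts spread by more than counting noise. At a mean of 50 to 100 counts the SD of log2 ratios was 0.43, and counting noise alone would give 0.25.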

Other observations

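The tests of the mitochondrial pattern were chosen only after the values they measure had been seen, and the lists of cholesterol synthesis, LXR target, SR protein and CLK, and Y-linked genes were chosen after the data were seen. The text gives 6 tests on 3 patterns. All 23 genes of the cholesterol synthesis list, which sterol-regulated transcription factors switch on together, were higher in replicate 2, with a median log2 ratio of 0.63. Idi1 had the largest ratio at 1.26, on 41 and 141 counts. The smallest were Hsd17b7 (0.06), Fdft1 (0.07) and Acat2 (0.19). In the second transcript table all 23 ratios were also above 0.

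The sterol pattern came to notice through 5 genes with high ratios, Idi1, Cyp51, Nsdhl and Insig1 among them. The 18 members not looked at before, known only to lie below the highest ratios, had a median of 0.60, higher than every matched random list (percentile 100.0), which argues against a pattern made by picking. Random lists matched on transcript length and GC content gave the same percentile, 100.0, for all 23 members, which argues against a length or GC bias. A lower sterol content of the cells in replicate 2 may be a source: the LXR targets Abca1 (-0.41), Abcg1 (-0.23), Apoe (-0.67) and Lpl (-0.33), which sterols switch on, had been seen to be lower, but 6 others, tested after that, were split 3 and 3 with a median of -0.09 at the 15.4 percentile, which leaves it open. Replicate and RNA input cannot be told apart, and no biological explanation is given by the design.

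Mitochondrial transcripts were lower in replicate 2. Reads that only moved between the mitochondrial protein-coding genes and their nuclear copy on chromosome 1 would leave the summed counts of both even, but these had a log2 ratio of -1.01 (95% range over resampled genes -1.12 to -0.93) and of -0.98 in the second transcript table, which argues against shared reads as the cause for the genes as a set. An earlier test, on genes with like counts in both tables, was dropped because it left out no gene of the pattern. Single genes do depend on the table: mt-Co2 had 0 counts in both replicates of the gene table and 330 and 0.565 in the second transcript table, while the pseudogene Gm28437 (chromosome 1, 24613189 to 24613971) had 880 and 557 in the gene table. More cytoplasmic RNA in replicate 1 may be a cause and stays open, since the cytoplasmic 7SL RNA had a log2 ratio of -0.76 but the nuclear RNA Scarna2 had -0.69 and ribosomal protein genes a median of -0.06 (-0.11 to 0.01), and no biological explanation was tested.

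Genes for SR proteins and CLK kinases, which regulate splicing, may give more of their signal to retained-intron transcripts than other genes do. Over 14 of them the median share was 63.2%, at the 99.3 percentile of lists matched on counts and on the number of annotated retained-intron transcripts (central 95%, 36.2% to 60.2%). Srsf11 had 91.6 ± 2.08%, Srsf7 80.0 ± 1.44%, Srsf3 79.0 ± 4.61% and Clk1 72.3 ± 1.73%, while Srsf4 had 38.3 ± 2.68% and Srsf1 39.8 ± 5.12%. Srsf5 (44.5 ± 1.22%) was known to be abundant when the list was written. No technical explanation was tested for this pattern beyond that matching. The share was taken in TPM, and the lists were not matched on transcript length.

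The sex of the mice was not collected. Xist held 161052 and 214110 counts. The 183 protein-coding genes on chromosome Y held 2 and 9 counts in the gene table, with 0 for Uty, Ddx3y and Eif2s3y and 0 and 2 for Kdm5d. The second transcript table gave chromosome Y genes 6488 and 6485 counts, 421 and 642 of them on Kdm5d.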
